A study of Talpa occidentalis with 24 samples.

How the data were processed

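Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on gonads of the Iberian mole, Talpa occidentalis, at postnatal day 7. Female moles of this species carry ovotestes, gonads with an ovarian and a testicular part, and the labels name 3 tissues: the ovarian part of the ovotestis, the testicular part of the ovotestis and the testis. Each tissue has 8 libraries, from 4 histone marks with 2 replicates per mark, 24 libraries in all. The marks are H3K4me3 (found at promoters), H3K4me1 (found at enhancers), H3K27ac (found at active promoters and enhancers) and H3K27me3 (deposited by Polycomb complexes).

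The deposited tables hold no read counts. Each assigns 1 of 7 named chromatin states to every stretch of the genome, and the authors combined the marks and both replicates of a tissue into 1 such segmentation. The state names are promoter, bivalent promoter, active enhancer, poised enhancer, Polycomb repression, undefined and gap, and they were used as the authors gave them. How each state relates to the marks, what the gap state covers and the depth behind each call are not given in the sources used here. The submitters' processing notes name STAR 2.6.1d and the mouse build mm9. Per the file headers, the segmentations of mouse ovary and testis were made with EpiCSeg, whose version is not given there; no header names the tool for the mole tables. The mole segments lie on 4454 scaffolds of an assembly named talOcc4, in bins of 200 bp that start and end at the same positions in the 3 tissues and cover 2099 Mb. The 19 scaffolds of at least 1 Mb hold 96.6% of these bases. Scaffolds are given below by their talOcc4 number, and positions count from 1.

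Because each tissue has 1 segmentation, there are no replicates at this level, the depth is unknown, and no test between tissues was run. Coverage of each state was computed as the percent of segmented bases. Intervals in brackets are 95% ranges over 1000 bootstrap resamples of 1 Mb blocks. They describe variation along the genome and leave out differences between animals and libraries. A scaffold shorter than 1 Mb counts as 1 block. Blocks are drawn independently, so the ranges do not reflect patterns that span a whole scaffold. Agreement between tissues was measured as the percent of bases in the same state and as the Jaccard index of each state, the bases in that state in both tissues over the bases in it in either. Both were set beside the values after 100 random circular shifts of 1 segmentation within each scaffold. These designs were fixed before the data were examined. The bases shared by 2 tissues as a share of the smaller of the 2 sets were added afterwards.

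The gene models deposited with the series lie on another assembly, talOcc3, and the gene table of the reference on MPIMG_talOcc4v2.1, and coordinates were not carried from either to talOcc4. The planned counts of genes by promoter state, the planned differences over gene lists and the naming of genes by chromatin change were therefore not computed. The rules that took their place were chosen after the data had been examined. Active coverage is the promoter plus the active enhancer state. A distal active enhancer is an active enhancer segment of at least 400 bp that lies more than 2 kb from any promoter or bivalent promoter segment of the 3 tissues, in place of a distance to gene starts. It was counted as present in 1 tissue only when it shared no base with an active segment of the other. Promoter segments of at least 400 bp were compared in the same way by the promoter state. Regions are named from adjoining windows of 100 kb with less than 50% of gap state in each tissue, as the 10 with the largest difference in active coverage in each direction; for the parts of the ovotestis, the testis also had to differ from the ovarian part in the same direction. Shares of segments carry Wilson 95% intervals, which cover counting only. Scaffolds 15 and 18 were left out in an alternative added after their profiles had been seen, and after a comparison with the order and length of sequences in the reference gene table, made to ask which chromosomes they belong to. That comparison relies on positions from another assembly, so its outcome is not reported, but it was known when these scaffolds were chosen for description and for leaving out.

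In the talOcc3 gene models, names came from the deposited annotation. Models of the same name were called tandem when they had several exons and lay on the same strand within 100 kb. The position ranges they matched on their targets also had to overlap over at least 50% of the shorter range. Whether the models matched the same target sequence was not checked. The 14 gene lists written before the data were examined hold 240 genes, of which 216 are named in the talOcc3 models and 225 in the reference table. Neighbouring genes were compared by name only, with 5 named neighbours on each side.

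The mouse segmentations belong to no labelled sample and enter no comparison between groups. The functions for overlap and counting were tested on a simulated pair of segmentations with 3000 elements, of which 1000 were made specific to 1 of them; 1000 were recovered, and 3 of 3 quantities with an exact answer came out as made. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives varied the minimum segment length, the rule for shared segments, the scaffolds included, the treatment of undefined and gap bases, and the scaling of active coverage.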

Results

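Chromatin state segmentations were compared between the ovarian part of the mole ovotestis, the testicular part of the ovotestis and the testis at postnatal day 7. Each rests on 8 ChIP-seq libraries and covers the same 2099 Mb of the talOcc4 assembly. The ovarian part was divided into 697647 segments, the testicular part into 639060 and the testis into 684094. There is 1 segmentation per tissue, so no difference below has a replicate check, and the depth is unknown.

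The active enhancer state covered less of the genome in the ovarian part than in either testicular tissue. It took 3.52% of segmented bases in the ovarian part [3.38 to 3.66], 4.88% in the testicular part [4.72 to 5.05] and 5.23% in the testis [5.06 to 5.42]. The promoter state went the other way, with 0.649% in the ovarian part [0.620 to 0.679], 0.573% in the testicular part [0.547 to 0.601] and 0.568% in the testis [0.541 to 0.594]. Active enhancer coverage of the testicular part was 1.39 times that of the ovarian part [1.36 to 1.42], and promoter coverage was 0.883 times [0.871 to 0.894]. Leaving aside scaffolds 15 and 18, promoter coverage was higher in the ovarian part on 17 of 17 scaffolds of at least 1 Mb, and active enhancer coverage was lower there on 16 of 17. Between the testicular part and the testis the promoter ratio was 0.990 [0.979 to 1.00]. The poised enhancer state covered 22.2%, 20.8% and 20.8% in the ovarian part, the testicular part and the testis. The bivalent promoter state covered 0.852%, 0.808% and 0.932% in the same order.

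**Figure D1:**
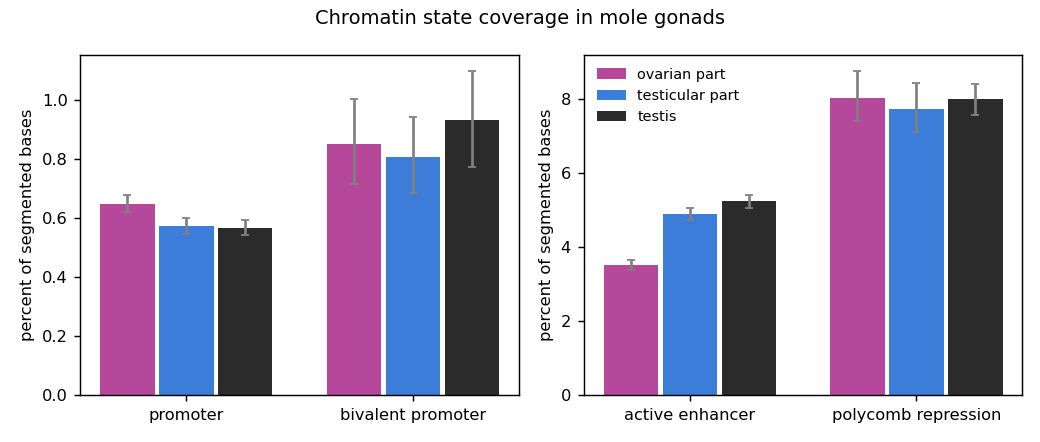
Percent of segmented bases in the promoter, bivalent promoter, active enhancer and Polycomb repression states in each tissue; bars show the coverage of 1 segmentation and error bars the 95% range over resampled 1 Mb blocks. Active enhancer coverage is 3.52% in the ovarian part, 4.88% in the testicular part and 5.23% in the testis, while Polycomb coverage lies between 7.74% and 8.04%.

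The Polycomb repression state covered similar shares of the whole genome but lay in different places. It took 8.04% of bases in the ovarian part [7.40 to 8.77], 7.74% in the testicular part [7.10 to 8.43] and 7.99% in the testis [7.58 to 8.40]. On scaffold 15, which is 88.9 Mb long, it covered 70.4% in the ovarian part, 66.6% in the testicular part and 1.77% in the testis. Without scaffolds 15 and 18, Polycomb coverage was 4.99% in the ovarian part, 4.85% in the testicular part and 7.94% in the testis, 1.59 times higher in the testis than in the ovarian part. On 17 of the 17 other scaffolds of at least 1 Mb it was higher in the testis than in either part of the ovotestis.

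Along scaffold 15, the Polycomb state exceeded 50% in 71 of 89 windows of 1 Mb in the ovarian part, in 66 in the testicular part and in 0 in the testis. The median window held 77.9% in the ovarian part, 81.0% in the testicular part and 0.440% in the testis. In the last 3 windows, from position 86000201 to 88923800, the testis held between 12.4% and 29.4%, the ovarian part between 16.8% and 37.2%, and the testicular part between 13.3% and 30.2%. They were set off by a limit of 12% in the testis, chosen after the profile had been seen. The highest other window of the testis held 10.7%. Low shares in the parts also occurred elsewhere, with 19.3% in the ovarian part and 4.72% in the testicular part from 49000201 to 50000200. In the ovarian part that was the lowest other window, so the 16.8% among the last 3 was not reached elsewhere. Of the scaffold 15 bases in the Polycomb state in the ovarian part, 67.2% were undefined in the testis and 24.1% were in the gap state. The gap state covered 29.7% of scaffold 15 in the testis, against 4.45% in the ovarian part and 4.42% in the testicular part. The bivalent promoter state covered 1.1% of scaffold 15 in the ovarian part, 0.710% in the testicular part and 0.0700% in the testis, while the promoter state covered 0.430%, 0.367% and 0.481%.

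Scaffold 18, 18.4 Mb long, differed at its start. In its first 4 windows of 1 Mb, positions 201 to 4000200, the gap state covered between 72.8% and 97.4% in the ovarian part and between 70.9% and 94.7% in the testicular part, but between 12.7% and 29.8% in the testis. Over the whole stretch the testis carried 14.1% of Polycomb state, 3.86% of poised enhancer and 0.50% of promoter state. In the other 15 windows the gap state reached at most 27.5% in the ovarian part, 19.1% in the testicular part and 20.2% in the testis.

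**Figure D2:**
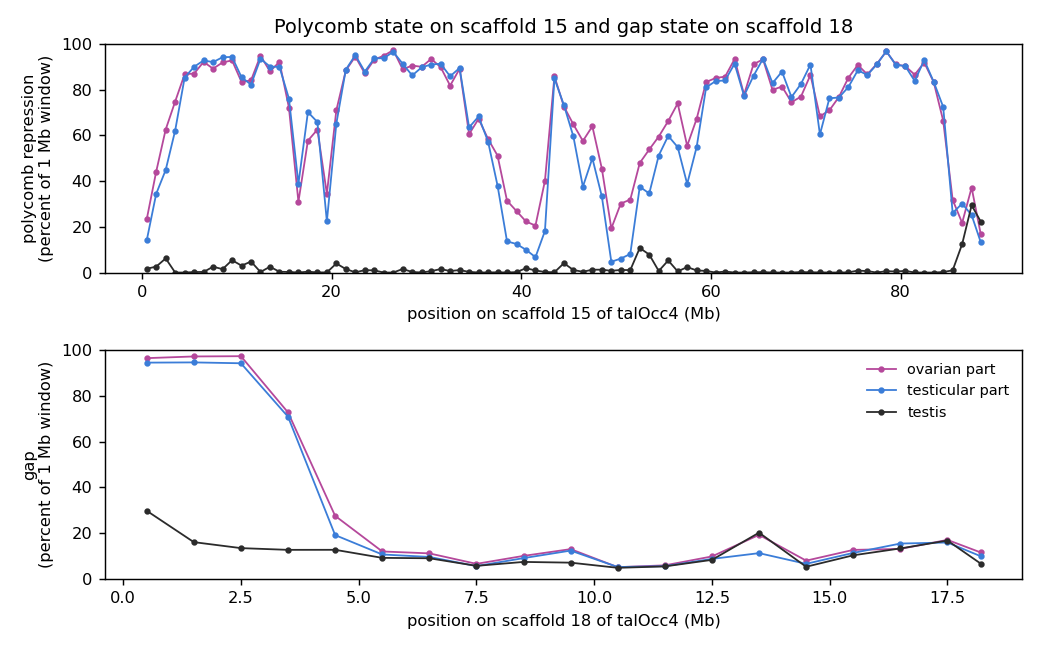
Percent of each 1 Mb window in the Polycomb repression state along scaffold 15 (top) and in the gap state along scaffold 18 (bottom), by position in Mb on talOcc4; each line is 1 tissue. The testis stays at or below 10.7% on scaffold 15 before its last 3 windows, and on scaffold 18 the ovotestis parts exceed 70% of gap state in the first 4 windows.

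The next comparison asked whether the testicular part of the ovotestis is closer to the testis or to the ovarian part it adjoins. For active enhancers the answer depended on the measure. The Jaccard index of the testicular part was 0.496 with the testis [0.490 to 0.502] and 0.415 with the ovarian part [0.409 to 0.421], a difference of 0.0809 [0.0752 to 0.0865]. The ovarian part and the testis shared least, with 0.367 [0.362 to 0.373]. Of the active enhancer bases of the testicular part, 68.7% were active enhancer in the testis and 50.5% in the ovarian part. Both measures are limited by unequal coverage, since the ovarian part had fewer such bases to share. As a share of the smaller set of each pair, whose denominator is another tissue in each pair, the order was the reverse. Of the active enhancer bases of the ovarian part, 70.1% were active enhancer in the testicular part [69.4 to 70.8]. Against the 68.7% of those of the testicular part in the testis [68 to 69.4], the difference was -1.35 percentage points [-2.26 to -0.404], where the Jaccard index gave a positive one. Unequal coverage affects this share too, because it can rise with the size of the larger set. Neither measure therefore settles which tissue is closer. Promoters had Jaccard indices of 0.690 for the testicular part and the testis, 0.640 for the parts of the ovotestis and 0.619 for the ovarian part and the testis, and shares of the smaller set of 82.0%, 83.2% and 81.9%. Of the promoter bases of the testicular part, 81.25% were promoter in the testis and 83.2% in the ovarian part, which had the most promoter state. Poised enhancers gave indices of 0.455, 0.422 and 0.394 and shares of 62.6%, 61.2% and 58.4%, so that both measures put the testicular part nearer to the testis.

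For the Polycomb state the parts of the ovotestis were closer, with a Jaccard index of 0.531 [0.505 to 0.555] against 0.320 for the testicular part and the testis [0.301 to 0.339]. Of the Polycomb bases of the testicular part, 70.7% were Polycomb in the ovarian part and 49.25% in the testis. The order of the indices rested on scaffolds 15 and 18: without them the indices were 0.391 and 0.409. These 2 values are not a tie on equal terms. Without the scaffolds the Polycomb state covered 4.99% in the ovarian part, 4.85% in the testicular part and 7.94% in the testis. Unequal coverage therefore limits the index with the testis more than that between the parts. Over all states, 76.1% of bases were in the same state in both parts of the ovotestis [75.8 to 76.4], 74.4% in the testicular part and the testis [73.8 to 75] and 70.8% in the ovarian part and the testis [70.2 to 71.4]. Without scaffolds 15 and 18 these were 75.8%, 76.9% and 73.2%, with the larger share of the testicular part then shared with the testis. Circular shifts gave on average 44.3%, 40.9% and 40.9% for the parts of the ovotestis, the testicular part and the testis, and the ovarian part and the testis. For the bivalent promoter state the difference in index between the testis and the ovarian part as partners of the testicular part was -0.00480 [-0.0277 to 0.0152], a range that includes 0. As a share of the smaller set it was 3.45 percentage points [1.60 to 5.16]. On scaffolds 18, 19 and 20 the bivalent index was 0.627 with the testis and 0.732 with the ovarian part. On the other scaffolds it was 0.625 and 0.604, the reverse order.

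**Figure D3:**
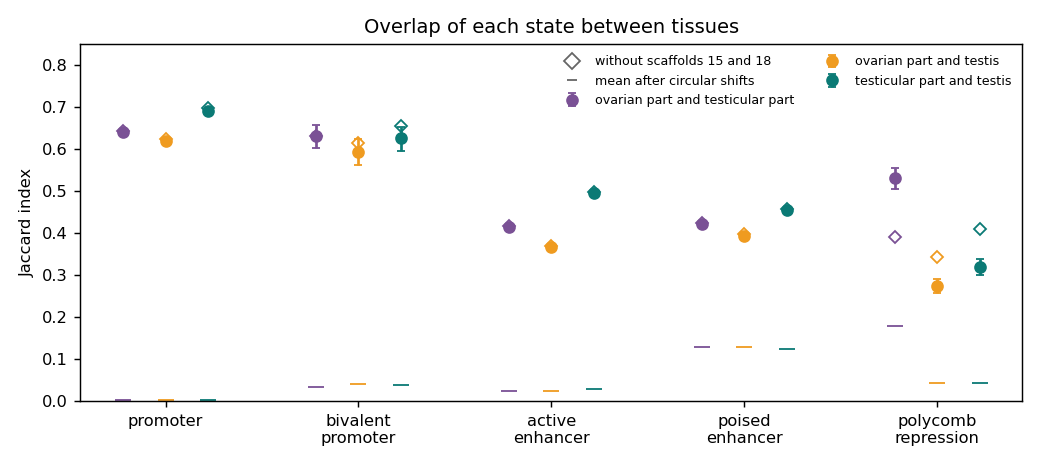
Jaccard index of 5 states for each pair of tissues; filled points are all scaffolds with the 95% range over resampled 1 Mb blocks, open diamonds leave out scaffolds 15 and 18, and dashes mark the mean after circular shifts. The testicular part and the testis have the highest index for promoters (0.690) and active enhancers (0.496), and the Polycomb index of the parts of the ovotestis is 0.531 with and 0.391 without the scaffolds.

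Distal active enhancers present in 1 tissue only were more numerous in the testicular tissues than in the ovarian part. The ovarian part also had the least active enhancer state, so unequal coverage limits this comparison. Of 42445 distal active enhancers in the testicular part, 19159 (45.1%, Wilson interval 44.7 to 45.6) shared no base with an active segment of the ovarian part. Of 34524 in the ovarian part, 10259 (29.7%, 29.2 to 30.2) were absent from the testicular part. With segments of at least 1000 bp in place of 400 bp these counts were 11580 and 3892. Against the testis, 12168 (35.2%) of the enhancers of the ovarian part and 13817 (32.6%) of those of the testicular part were found in the first tissue only. The testis had 41277, of which 20314 (49.2%) were absent from the ovarian part and 13239 (32.1%) from the testicular part. After circular shifts at least 88.1% of the enhancers were unshared in each of these 6 comparisons.

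The rules for these enhancers exclude the promoter, bivalent promoter and active enhancer states from their bases in the other tissue. Among the states that remain, most of the bases were in the poised state. That state covered 22.15% of all segmented bases in the ovarian part and 20.85% in the testicular part. Of the bases of enhancers found only in the testicular part, 92.8% were poised in the ovarian part, and of those found only in the ovarian part, 90.8% were poised in the testicular part. For enhancers of the testis against the ovarian part the figure was 83.9%, with a further 14.0% undefined. Merged over the tissues, 61688 distal enhancer regions were formed, of which 17236 (27.9%) were active in all 3 tissues. A further 9241 (15%) were shared by the testicular part and the testis, 4210 (6.83%) by the parts of the ovotestis and 2245 (3.64%) by the ovarian part and the testis. The remaining regions were active in the testis only (11216), the testicular part only (9819) or the ovarian part only (7721).

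Promoter segments were more often specific to the ovarian part, which also had the most promoter state, so unequal coverage limits this comparison too. Of 16183 promoter segments there, 2624 (16.2%, Wilson interval 15.7 to 16.8) shared no promoter base with the testicular part, against 943 of 13918 (6.78%, 6.37 to 7.21) in the opposite direction. These counts depended on the minimum length: they were 268 and 92 for segments of at least 1000 bp and 4967 and 1900 with no minimum, against 2624 and 943 for 400 bp. Of the bases of promoter segments found only in the ovarian part, 35.8% were active enhancer, 25.9% poised enhancer, 13.35% undefined, 13.2% Polycomb and 10.4% bivalent promoter in the testicular part. Of the promoter segments of the ovarian part, 372 were bivalent in the testicular part over at least 50% of their length, and 384 were in the Polycomb state there over at least 50%; the opposite changes numbered 89 and 98. These segments were short, with a median of 400 bp for those found only in the ovarian part and 600 bp for those shared.

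The regions named next are extremes among 19803 windows, chosen on the difference that is then given, so large values follow from the choice. Over all windows the ovarian part minus the testicular part had a mean of -1.33 percentage points and an SD of 4.12. No replicate shows how much of the extremes is noise in the calls. The window with the largest excess of active coverage in the ovarian part over the testicular part lay on scaffold 12 at 73700201 to 73800200, where the active states covered 45.4% in the ovarian part, 13.0% in the testicular part and 4.40% in the testis, and the Polycomb state covered 14.8%, 30.2% and 43.0%. Scaffold 11 at 32100201 to 32200200 held 79.6% of active states in the ovarian part, 54.6% in the testicular part and 46.6% in the testis. Scaffold 13 at 97400201 to 97500200 held 38.4%, 13.8% and 6.0%, with 37.0% of Polycomb state in the testis. Adjoining windows on scaffold 2, from 18600201 to 18800200, held 37.4% and 36.2% in the ovarian part and 13.4% and 11.2% in the testicular part.

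In the other direction, scaffold 6 at 86400201 to 86500200 was active over 10% in the ovarian part, 52.2% in the testicular part and 44.2% in the testis. Scaffold 1 at 27000201 to 27100200 held 19%, 56.4% and 48.2%. Scaffold 3 at 80100201 to 80200200 held 8.0%, 44.6% and 59.4%, and scaffold 8 at 3000201 to 3100200 held 3.4%, 38.6% and 47.8%. The windows named so far also had to differ in the same direction from the testis, which left out 2 windows with a larger excess than the smallest of the 10 and 0 with a larger deficit. The larger of these excesses was 28.6 points, on scaffold 10 at 89400201 to 89500200, where the active states covered 48.4% in the ovarian part, 19.8% in the testicular part and 53.6% in the testis. Of 19803 windows, 464 were at least 10 percentage points less active in the ovarian part than in both other tissues and 64 were at least 10 points more active. Both comparisons use the same ovarian segmentation and are not independent. They also use unscaled coverage, and the active states covered 4.165% of the genome in the ovarian part, 5.45% in the testicular part and 5.80% in the testis. Unequal totals can therefore raise the first count over the second, and the counts were not repeated after scaling. The choice of windows depended on the settings: after each tissue was scaled to the same active total, 8 of the 10 with an excess in the ovarian part and 7 of the 10 with a deficit were among the 10 largest again. With windows of 40 kb, 6 and 3 of them overlapped the 10 largest, and with windows of 200 kb, 6 and 6. The same scaling changed the excess on scaffold 11 at 32100201 to 32200200 from 25 to 46.8 points over the testicular part and from 33 to 56.95 points over the testis. The genes in these windows are not named, because the gene models used here lie on other assemblies.

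**Figure D4:**
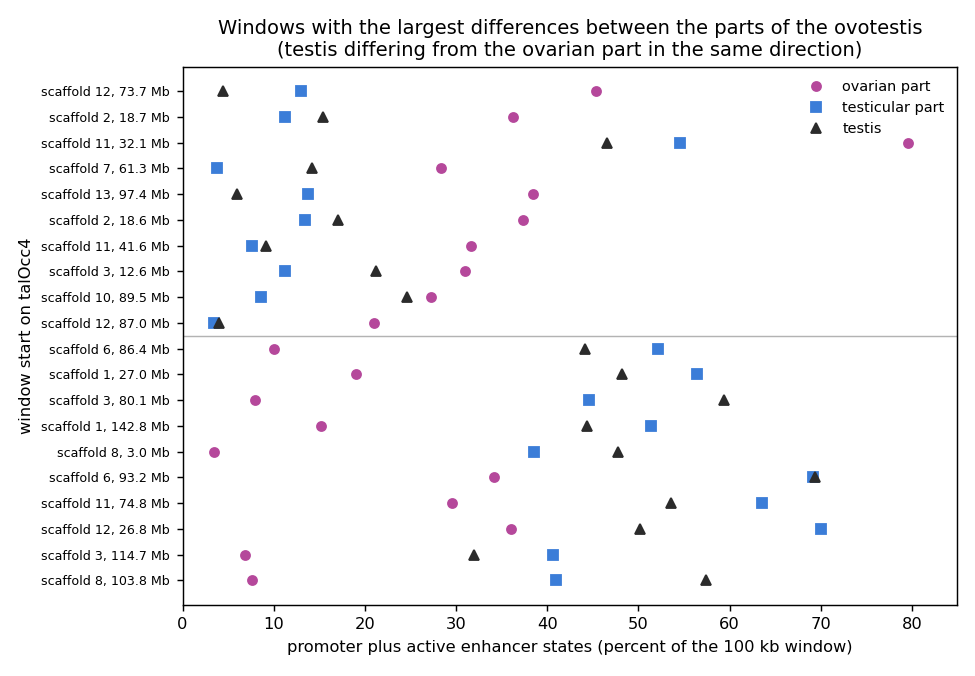
Active coverage (promoter plus active enhancer states, percent of a 100 kb window) in the 10 windows with the largest excess in the ovarian part (upper block) and the 10 with the largest deficit (lower block) against the testicular part, among windows where the testis differed from the ovarian part in the same direction; each symbol is the value of 1 tissue. On scaffold 6 at 86400201 the values are 10% in the ovarian part, 52.2% in the testicular part and 44.2% in the testis.

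Between the testicular part and the testis, the window with the largest excess in the testicular part lay on scaffold 16 at 79800201 to 79900200, with 36.4% of active states against 7.60% in the testis and 49.4% in the ovarian part. The Polycomb state covered 46.6% of it in the testis and 10.8% in the testicular part. Scaffold 3 at 43200201 to 43300200 was active over 37.0% in the testicular part, 11.4% in the testis and 13.6% in the ovarian part. In the opposite direction, scaffold 2 at 49500201 to 49600200 was active over 41.4% in the testis, 3.80% in the testicular part and 5.60% in the ovarian part. Scaffold 10 at 40400201 to 40500200 was active over 7.0% in the ovarian part, 30.6% in the testicular part and 63.6% in the testis.

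The gene models on talOcc3 describe the gene content of the mole genome and carry no tissue values. They comprise 23336 models under 18052 names. Among the fixed lists, 22 genes had more than 1 model, and 2 of these had tandem models: CYP17A1, which encodes an enzyme of androgen synthesis, and TDRD9, a germ cell gene of the transposon-silencing pathway. CYP17A1 had 3 tandem models on the minus strand of talOcc3 scaffold 11, at 45100228 to 45105611 with 8 exons, at 45117841 to 45121591 with 6 exons and at 45139044 to 45144553 with 8 exons. The models with 8 exons matched positions 173 to 1696 of their targets and the model with 6 exons positions 698 to 1696 of its target. They lay between WBP1L and BORCS7. The TDRD9 models matched positions 330 to 2014 and 1287 to 2720 of their targets, so these ranges overlap in part. In the gene table of MPIMG_talOcc4v2.1, 2 protein-coding genes without a symbol lie between WBP1L and BORCS7, and CYP17A1 is not used there as a symbol. Over all names, 278 of 2362 with more than 1 model had tandem models.

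**Figure D5:**
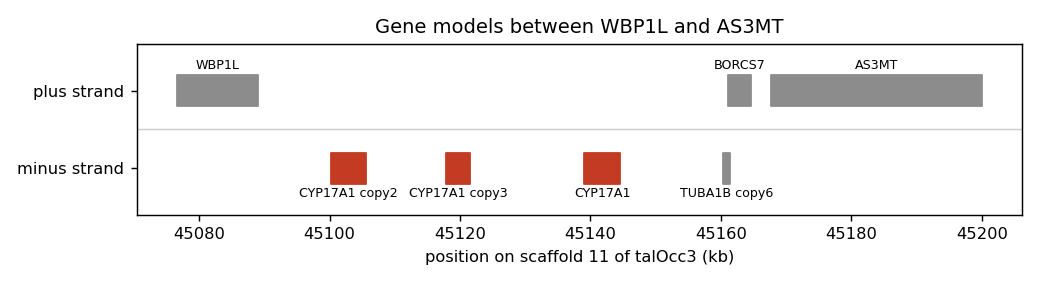
Gene models from WBP1L to AS3MT on scaffold 11 of talOcc3, drawn to scale by position in kb and by strand, with the 3 models named CYP17A1 in red. The models start at 45100228, 45117841 and 45139044.

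FGF9, which encodes a growth factor needed for testis development in mice, lay on talOcc3 scaffold 38 at 11731991 to 11761319 on the minus strand, with 3 exons. Its nearest neighbours were MICU2, at a distance of 132.3 kb, and on the other side RUBCNL, at 1326 kb. RUBCNL and MICU2 are also the nearest named protein-coding neighbours of FGF9 in the table of MPIMG_talOcc4v2.1. Of 185 list genes with 1 model in talOcc3 and 1 entry in that table, 180 shared at least 1 named neighbour on both sides, 3 on 1 side and 2 on neither. Of a further 19 with several models, compared at the model without a copy number, 16 shared them on both sides and 3 on neither. Among these 3, HOXC12 had no neighbour of another name on its talOcc3 scaffold and so could share none.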

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

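No paired analysis was possible because each segmentation pools both replicates of a tissue; for the same reason no replicate could be left out, and depth is unknown. The alternatives set beforehand for gene starts, gene lists and named genes were not run, since gene positions on talOcc4 were not used here. The alternatives without scaffolds 15 and 18, with gap bases left out, with overlap over the smaller set, with other distances from promoters, for promoter segments and with scaled windows were chosen after seeing the data. Where causes are not named below, the cause was not tested. Keeping scaffolds of at least 1 Mb left 32 of 32 values inside their ranges, and sharing within 1 kb, sharing by 50% of a segment, a distance of 10 kb or no distance rule left each count within 1.5 times.

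Without scaffolds 15 and 18, the share of bases in the same state in the testicular part and the testis, minus that in both parts, reversed from -1.68 to 1.17 percentage points, and for the Polycomb Jaccard index from -0.211 to 0.0183; for the bivalent index it moved to 0.0244. With shared bases over the smaller set in place of the Jaccard index, the same difference reversed to -0.0135 for active enhancers and -0.0118 for promoters. It moved to 0.0345 for bivalent promoters. Unequal coverage limits the Jaccard index by construction and can raise the share of the smaller set. Again without scaffolds 15 and 18, agreement of the testis became 73.2% with the ovarian part and 76.9% with the testicular part. The Polycomb indices became 0.391 (both parts), 0.345 (ovarian part and testis) and 0.409 (testicular part and testis), and for the last pair the promoter and bivalent indices became 0.698 and 0.656. Coverage without these scaffolds became 3.69%, 5.12% and 5.47% for active enhancers in the ovarian part, testicular part and testis. It became 4.99% and 4.85% for Polycomb in the parts, and 0.706% and 0.771% for bivalent promoters in the ovarian part and testis. Without bases undefined in both tissues, agreement was 53.4% between the parts, 45.9% for the ovarian part and testis and 51.2% for the testicular part and testis. Leaving out gap bases, active enhancers covered 3.77%, 5.23% and 5.68%, promoters 0.697%, 0.614% and 0.616%, and Polycomb 8.68% in the testis. Segments of at least 400 bp gave promoters 0.609%, 0.543% and 0.537%.

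Longer minimum lengths keep fewer segments by construction. At 1000 bp, distal enhancers only in the ovarian part numbered 3892 against the testicular part and 5118 against the testis; only in the testicular part, 11580 against the ovarian part and 7721 against the testis; only in the testis, 13495 against the ovarian part and 8013 against the testicular part. Promoter segments in the same order numbered 268, 342, 92, 122, 184 and 176, and with no minimum length 4967, 5108, 1900, 2444, 2051 and 2447. Of the 18 window differences rescaled to the same active total, 15 moved by more than 1 SD over windows.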

Other observations

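All tests in this part were chosen after the pattern had been seen; for 1 of them, the state in the ovotestis of bases marked in the testis at the start of scaffold 18, the bounds were written before its result.

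The bivalent promoter state was spread unevenly over scaffolds. Scaffolds 18, 19 and 20 make up 1.1% of the segmented bases but held 22% of the bivalent bases of the ovarian part, 21.0% of those of the testicular part and 26.6% of those of the testis. Scaffold 2, with 7.31% of the segmented bases, held 18.5%, 21.2% and 18.6%. On scaffold 20 the state covered 44.4%, 37.1% and 41.8%. Bivalent segments longer than 5 kb numbered 570, 546 and 656 over the genome, of which 174, 165 and 226 lay on these scaffolds. The longest active enhancer segment of the testis lay on scaffold 8 at 36969201 to 37025600, 56.4 kb long, and 87.6% of it was active in the ovarian part and 91.8% in the testicular part.

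In the mouse tables, given as values only, the active enhancer state covered 12% of the ovary segmentation and 9.64% of the testis segmentation, and the Polycomb state 27.8% and 25.7%. On the X chromosome the Polycomb state covered 50.8% in the ovary table and 31.4% in the testis table, and on the other chromosomes apart from the Y and mitochondrial ones 26.5% and 25.5%. On the Y chromosome the gap state covered 98.8% and 92.8%. The mouse tables had the same state at 51.7% of bases.

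The Polycomb state covered most of scaffold 15 in both parts of the ovotestis and hardly any of it in the testis. Fewer reads on this scaffold in the testis might hide active marks too. The promoter and active enhancer states together covered 1.49% of it there, against 0.777% in the ovarian part and 0.929% in the testicular part. Each base has 1 state, so bases in the Polycomb state in the parts could not be active there, and this comparison cannot decide whether reads were fewer. The gap state covered 29.7% of the scaffold in the testis, against 4.45% in the ovarian part and 4.42% in the testicular part. What the gap state measures is not given, so whether reads were lost from the scaffold stays open. A lower rate of Polycomb calls in the testis in general would lower its share on other scaffolds too. Of 18 other scaffolds of at least 1 Mb, 0 had less Polycomb state in the testis than in both parts, so its calls were not fewer there. Depth is unknown, and the signal on scaffold 15 could itself lower the calls of the parts elsewhere. This count therefore cannot decide whether calling was less sensitive in the testis. With 1 segmentation per tissue and unknown depth, other differences in calling cannot be excluded. A difference in tissue or in the sex of the animals, such as an X chromosome present in different copy number, stays open as an untested hypothesis: which chromosome scaffold 15 belongs to is not reported here.

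The start of scaffold 18 was in the gap state in both parts of the ovotestis and not in the testis. If low coverage of the parts in general put bases in the gap state, their gap share would be raised elsewhere too. There are 17 scaffolds of at least 1 Mb other than 15 and 18. The gap share exceeded that of the testis on 1 of them in the ovarian part and on 2 in the testicular part. These counts argue against a general excess of gap calls in the parts. What the gap state measures is not given, so they do not decide about read coverage. A candidate explanation is sequence that the animals with an ovotestis lack. Of the 810.4 kb of the stretch in a marked state in the testis, 62.2% were in the gap state in both parts, against 0.118% on scaffolds other than 15 and 18. That value lies between the bounds written beforehand, over 80% if the sequence were missing and under 50% if not, so the hypothesis stays undecided. Split by window after that result had been seen, the share was 90.5% over windows 1 to 3 and 21.6% in window 4, which held 332.8 kb of the marked bases; the bounds and the stretch were left as they were.

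The testicular part had more active enhancer state than the ovarian part. A segmentation that calls each active state more readily might also raise promoter coverage, which was 0.883 times that of the ovarian part. Each base has 1 state, however. Of the promoter bases of the ovarian part, 14.1% were active enhancer in the testicular part, against 9.55% in the opposite direction. More active enhancer calls can therefore take bases from the promoter state, so this ratio cannot decide the question. A lower threshold between poised and active enhancers in the testicular part was also tested. Of the bases of enhancers found only there, 92.8% were poised in the ovarian part, but the opposite share was 90.8%, so this value does not speak for a threshold shifted in 1 tissue. The threshold alone would also leave under 10% of the enhancers of the ovarian part active only there, and the share was 29.7%, so that condition was not met. Because 1 segmentation per tissue does not separate that share from noise in the calls, a contribution of the threshold cannot be told apart from a change at the enhancers themselves. A difference in tissue composition was not tested.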
